A study of Mus musculus with 20 samples.

How the data were processed

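Per the labels, C57BL/6 mice were exposed to 50 ppm benzene for 5 hours a day from embryonic day 0.5 to day 17.5, when tissue was collected, and 1.3 micrograms of total RNA went into each library. The 16 placenta libraries were made with NEBNext Ultra II and the 4 decidua libraries with the QuantSeq 3' FWD kit, so the 2 tissues were never compared with each other. The deposited tables hold raw gene counts, with no normalization. Processing tools listed by the authors are bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2, HTSeq 2.0.1, DESeq2 and edgeR, without saying which tool counted which tissue, and builds GRCm38 and mm10. The placenta tables hold 49315 Ensembl identifiers, 48970 of which matched a symbol in GENCODE vM21 or the gene table. The decidua table holds 35976 symbols, 26683 of which matched the annotation, 27 were changed into dates by a spreadsheet and 2 occur more than once. These unmatched names stayed in the table but in no gene list.

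Samples were grouped by sex and exposure (4 placentas per group) and by exposure (2 decidua libraries per group), as the sample titles give them. Control placentas came from control mothers 1 (replicates 1 and 2 of each sex) and 2 (replicates 3 and 4), and benzene placentas from benzene mothers 1 and 2 in the same way. No mother was given for the decidua. The code of decidua control replicate 1 begins with B1, as the benzene codes begin with B2 and B3, while the other control's begins with Th158, and benzene replicate 1 was on lane L002 and the other 3 on L001. The groups in the titles were kept, and whether code or lane matters could not be checked. Sex was checked with Xist and Y-linked genes, and no library was left out. Copies were searched for among the 26 pairs of libraries of the same group: the chi-square per degree of freedom was 10.5 to 167, so no pair was a resequenced copy.

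Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 0.916 to 1.06 in placenta and 0.94 to 1.1 in decidua), the filterByExpr filter (17392 and 12478 genes tested), quasi-likelihood F tests and Benjamini-Hochberg adjustment at 0.05. All 16 placentas were fitted together with 4 group means (12 residual degrees of freedom) and the decidua apart (2 degrees). The 6 comparisons were the sex difference (female minus male) in control and in benzene placentas, the benzene effect (benzene minus control) in each sex, their interaction (female minus male effect) and the benzene effect in decidua. Standard errors of log2 values are the size of the log2 value over the root of F. CPM of single genes are on TMM-scaled library sizes, and summed list CPM in the figures are on total counts. The 41 gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 where 5 or more members were tested, 39 in placenta and 35 in decidua, and again with the correlation between genes estimated. With median-ratio scaling every called list kept its direction. Groups, tests, lists and the rule for naming genes were set before the data were examined, except the list of 23 adult liver genes and the genes said to be chosen later. Genes were named when called, with an average log2 CPM of at least 1 and no overlap between groups (up to 10 per direction), when among the 4 smallest p of a list, or, with fewer than 5 calls, when among the 10 smallest p. Coordinates are from GENCODE vM21 on GRCm38.

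Littermates were checked for likeness as correlations of expression after removing group means: the mean r was 0.131 within control litters and 0.279 within benzene litters, against -0.112 and -0.269 between litters. Replicate numbers were checked too. In benzene placentas the female and male of the same number had r 0.366 to 0.665 (mean 0.529), and 8 of 8 libraries were most like the library of their own number. Each such pair also shared its mother and the letter L or R of its sample code, so number cannot be told from these. The fit with the pair as a block is given beside that comparison.

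Alternatives for each comparison were other scalings (median-ratio size factors and upper quartile), no filter, other thresholds, DESeq2 1.42.0, voom with the mother as a random effect (correlation within mother 0.0814), counts summed per mother, the mother or replicate number as a block, removal of GC and length trends, tissue-marker covariates, leaving out X and Y genes or libraries with more than 5000 CPM of Afp, and leaving out each library or litter. On simulated data made from these counts, edgeR recovered 58.2% and 67.2% of genes changed by a factor of 2 in the control and benzene sex comparisons, 65.7% and 73.1% in the female and male benzene comparisons, 44.8% for the interaction and 11.9% in decidua, where a factor of 4 gave 63.6%. The simulated libraries had no litter effect, so recovery of a benzene effect among litters that differ was not tested. A list of genes raised by a factor of 1.5 was found by camera at the preset correlation (adjusted p 5.22e-96), where 0 of 38 other lists were called, and had a p of 3.53e-10 with the correlation estimated. Genes were drawn independently of each other there, so this does not test false list calls where genes vary together. Intervals of list medians came from 10000 bootstrap draws and comparisons with random gene sets from 1000 sets. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.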

Results

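Placentas and decidua of mice carried through pregnancy with or without benzene were compared as gene counts. The 16 placentas came from 4 mothers, 2 per exposure, and each mother gave 2 female and 2 male placentas, so each group of sex and exposure held 4. Total counts per placenta were 20.2 to 22.9 M in control females, 18.7 to 21.4 M in control males, 21.9 to 24.3 M in benzene females and 20.3 to 21.8 M in benzene males. The 4 decidua libraries, 2 per exposure, held 2.1 to 3.4 M (M, 1e6 counts).

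Sex-linked transcripts matched the stated sex of all 16 placentas. Xist, the X-inactivation transcript, lay at 760 to 877 counts per 1e6 counts (CPM) in females and 47.7 to 119 in males. Ddx3y lay at 39.3 to 56.5 CPM in males and 0.0798 to 1 in females. In a principal component analysis of the placentas, component 1 (47.9% of the variance) followed yolk sac genes such as Afp. Component 2 (27.6%) set the 4 placentas of benzene mother 2 apart from the other 12, and component 3 (5.62%) followed sex. A component that parts 1 litter from the rest thus carried more of the variance than the one that follows sex, and each exposure rested on 2 litters.

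How do female and male placentas differ without exposure? Control male placentas held far more inflammatory transcripts than control females. Il1b, which encodes the cytokine interleukin-1 beta (GRCm38 chromosome 2, 129364570 to 129371139), averaged 12 ± 0.462 CPM (SD, n = 4) in males and 0.884 ± 0.14 in females, a log2 difference, female minus male, of -3.75 (SE 0.28). Acod1, the itaconate-making enzyme of activated macrophages (chromosome 14, 103046977 to 103056573), averaged 16.1 ± 2.32 CPM in males and 0.397 ± 0.277 in females (-5.34, SE 0.48). The chemokine Ccl4 (chromosome 11, 83662584 to 83664683) averaged 4.95 ± 0.651 and 0.0937 ± 0.0535 CPM (-5.63, SE 0.54). Of 20 tested inflammatory cytokines and NF-kB targets, 8 were higher in males and 0 in females, 8 also when adjusted over the list alone, among them Ccl3 (-4.05), Ccl2 (-2.56) and Tnf. The list as a whole was lower in females (camera, Benjamini-Hochberg adjusted p = 9.71e-76), also with the correlation between its genes estimated (p = 1.85e-08). Also higher in males were the myeloid receptor Clec4e (-4.79), the cystine transporter Slc7a11 (-1.89) and the chemokine Cxcl10 (-4.18), the 1 called gene among 31 interferon-stimulated genes.

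Macrophage markers did not share the size of that difference. Their median over 17 genes was -0.12, edgeR called 0 of them, and the list was not called (camera adjusted p = 0.0862). On the sex chromosomes, Kdm5d, Ddx3y, Uty and Eif2s3y were higher in males (-5.97 to -6.52) and Xist (X, 103460366 to 103483254) was 10.9-fold higher in females (3.44, SE 0.28). Among 14 genes that escape X inactivation, Xist and Ogt were higher in females at the threshold over all genes, and 8 were higher and 1 lower when adjusted over the list alone (median 0.36, camera adjusted p = 1.6e-21, estimated-correlation p = 1.85e-06). Ogt, the O-GlcNAc transferase (X, 101640060 to 101684351), averaged 385 ± 28.6 CPM in females and 218 ± 11.7 in males (0.82, SE 0.13). Taf1 (0.56) and Rps4x (0.34), also on the X, and the calcium-binding S100a6 (0.62) were higher in females. In all, edgeR's quasi-likelihood test called 35 of 17392 genes, 6 higher in females and 29 in males (smallest Benjamini-Hochberg adjusted p 1.03e-06, 583 genes at unadjusted p under 0.05). Within the litters of control mothers 1 and 2, taken alone, the Il1b difference was -3.67 and -3.84, Acod1 -5.09 and -5.69, and Ogt 0.79 and 0.85, and each litter gave 21 calls. Small list shifts upward in females for spongiotrophoblast, glycogen cell, erythroid, ribosomal protein, oxidative phosphorylation and heat shock genes, and downward for interferon genes, were called at the preset correlation only (estimated-correlation p 0.018 to 0.407). The calls of Rps4x, S100a6, Slc15a3, Slc7a11 and Taf1 were each lost in at least 1 refit without 1 library.

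How do they differ under benzene? The inflammatory difference was there again, with the same sign. Il1b averaged 9.13 ± 2.95 CPM in benzene males and 1.31 ± 0.425 in benzene females (-2.80, SE 0.26), Acod1 12.5 ± 4.73 and 0.294 ± 0.132 (-5.40, SE 0.49), and Ccl4 4.04 ± 1.99 and 0.173 ± 0.137 (-4.51, SE 0.50). Of the 20 inflammatory genes 7 were higher in males, and 9 higher in males and 1 higher in females when adjusted over the list alone, with Ccl3 (-3.12) and Tnf (-2.02) among the 7 (camera adjusted p = 4.69e-28, estimated-correlation p = 5.68e-06). Xist (3.38, SE 0.28), Ogt (0.74) and, outside the escape list, Bcorl1 (0.67) and Taf1 (0.55) on the X were higher in females. The 4 Y-linked genes differed by -6.52 to -7.27.

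Benzene placentas of the 2 sexes also differed in genes not called between the sexes in controls, such as Hmcn1, Trib3 and Airn, although the sex-by-benzene interaction of these genes (1.67, -0.77 and 0.52) was not called either. Hmcn1, which encodes the matrix protein hemicentin-1 (chromosome 1, 150562524 to 150993435), averaged 5.65 ± 1.52 CPM in females and 2.57 ± 0.543 in males (1.13, SE 0.20). Trib3, a target of the unfolded protein response (chromosome 2, 152337422 to 152344032), averaged 11.6 ± 1.23 in females and 19.5 ± 3.87 in males (-0.75, SE 0.14). The imprinted noncoding RNA Airn (chromosome 17, 12741311 to 12860136) was higher in females (0.51, SE 0.08); it overlaps Igf2r on the other strand and no strand was stated for the counts, so reads may belong to either gene. Airn is the 1 called gene of 26 imprinted genes (3 when adjusted over the list alone). Trib3 was the 1 called gene of 22 in the unfolded protein response, 13 of which were lower in females when adjusted over the list alone (median -0.43, camera adjusted p = 2.81e-11, estimated-correlation p = 0.00692 before adjustment), with Ddit3 at -0.50, Calr at -0.48 and Atf4 at -0.23, not called as single genes. With the correlation estimated, the escape and inflammatory lists were called and 0 of the other 14, the unfolded protein response included. Giant cell (median -0.39), spongiotrophoblast (-0.53) and pregnancy-specific glycoprotein lists (-0.52) lay lower in females, and smooth muscle (0.78), proliferation (0.51), endothelial (0.46) and macrophage lists (0.45) higher, each with 0 called genes by edgeR and with estimated-correlation p between 0.0317 and 0.0868. Female benzene replicate 3 carried much of the smooth muscle and proliferation shift, the sex difference being 0.43 and 1.81 for Myh11 and 0.83 and 2.03 for Top2a within the litters of benzene mothers 1 and 2. Members of the other lists with the smallest p were Prl2a1 (-0.59), Hand1 (-0.61), Emcn (0.87), Tek (0.65) and Mrc1 (0.81). Mesenchyme, decidual stroma, labyrinth, imprinted and angiogenesis lists also lay higher in females and the hypoxia list lower (estimated-correlation p 0.0874 to 0.293).

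The test called 29 genes, 6 higher in females and 23 in males (edgeR quasi-likelihood, smallest Benjamini-Hochberg adjusted p 4.4e-07, 2202 at unadjusted p under 0.05). Within the litters of benzene mothers 1 and 2 the Il1b difference was -2.91 and -2.61, Hmcn1 1.03 and 1.20, Trib3 -0.52 and -0.97, and Airn 0.53 and 0.48, with 17 and 114 calls. Female and male placentas of the same replicate number were matched in this group (r 0.366 to 0.665 after removing group means), and a fit with those pairs as a block called 18 genes, 3 higher in females (Xist, Ogt and Hmcn1) and 15 in males. Airn, Bcorl1, Taf1 and Trib3 were not called with the pairs as a block. The calls of Airn, Bcorl1, Hmcn1, Ogt, Taf1 and Trib3 were each lost in at least 1 refit without 1 library. Of the genes higher in males, 20 were called in both exposures (0.0384 expected, Fisher exact p = 6.79e-57), 15 of them not sex-linked. Of those higher in females 3 were shared (0.00207 expected, Fisher exact p = 4.56e-10), 0 outside the sex-linked genes. Both comparisons took the spread of each gene from the same fit, and the Fisher test treats genes as independent, so these p can be too small.

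**Figure D1:**
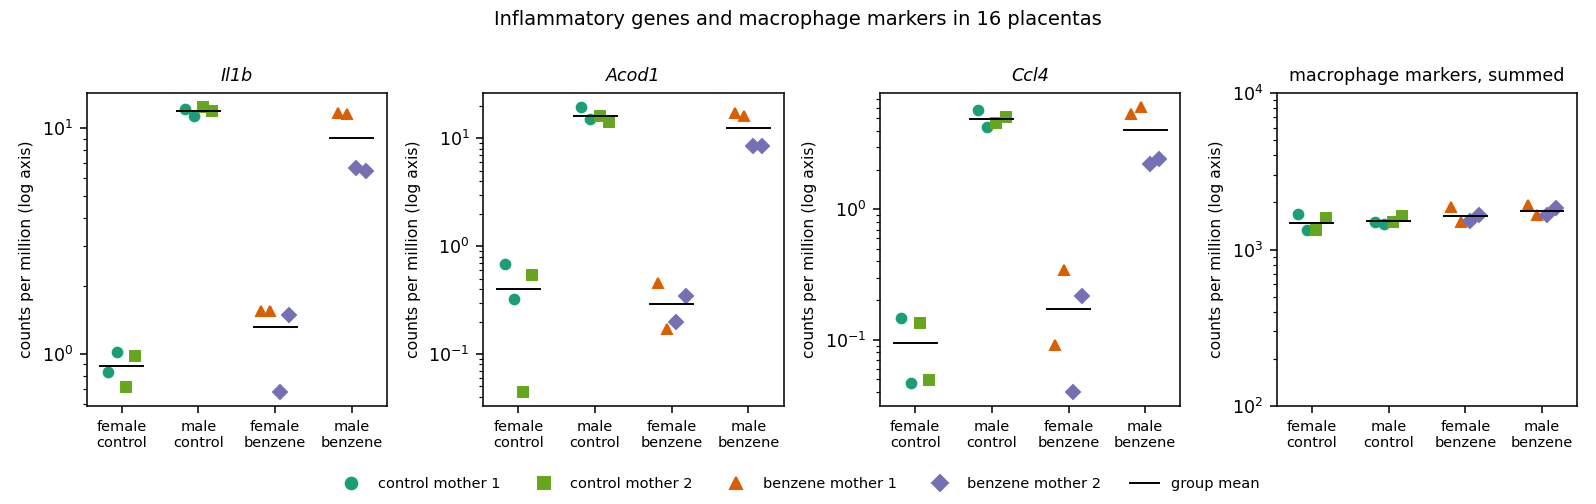
Il1b, Acod1, Ccl4 and summed macrophage markers per placenta in CPM on log axes, by sex and exposure, coloured by mother, with bars at group means. The 3 inflammatory genes are higher in males in every litter, while the summed macrophage markers overlap between the sexes. Csf1r alone, at 880 to 1540 CPM over the placentas, makes up most of that sum, so the panel says little of the lower markers.

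What did benzene change in female placentas? No single gene passed the threshold in females, and the direction of groups of genes is all that can be described. edgeR's quasi-likelihood test called 0 genes (smallest Benjamini-Hochberg adjusted p 0.4), with 1383 at unadjusted p under 0.05. The nominal chance count is 870, but other splits of the same 8 females into 4 and 4, fitted later, gave 239 to 2778. The 1383 are thus no sign of a benzene effect. DESeq2 called 46, 23 in each direction, and 0 were called by voom with the mother as a random effect or by counts summed per mother. The smallest unadjusted p belonged to the transporter Slc29a4, at 4.11 ± 2.54 CPM with benzene and 0.696 ± 0.0983 without (2.55, SE 0.46). Next came the sulfotransferase Sult2b1 (1.35, SE 0.26), the cytokine receptor-like factor Crlf1 (1.12, SE 0.21), the complement receptor C5ar2 (-0.96, SE 0.19) and the stress regulator Nupr1 (-0.59, SE 0.13). Labyrinth markers leaned upward (median 0.30), with Syna, which encodes syncytin A, at 1.37, Gcm1 at 0.80 and Gjb2 at 0.56, but the rise lay mostly in the females of benzene mother 2: Syna was at 64.2 and 51.1 CPM there, at 20.3 and 15 in the females of benzene mother 1 and at 10.6 to 20.2 in control females, and Gjb2 at 810 and 925, 486 and 484, and 378 to 520. Smooth muscle (0.55), decidual stroma (0.50, with Hand2 at 0.71), proliferation (0.32), endothelial (0.19) and oxidative phosphorylation genes (0.07) leaned the same way, and pregnancy-specific glycoproteins (-0.21) and spongiotrophoblast genes (-0.17) the other. These 8 lists passed at the preset correlation of camera and 0 with the correlation estimated (p 0.0704 to 0.476), and edgeR called 0 of their genes. They rest on few libraries: 4 of the 8 stayed called without female benzene replicate 3, where smooth muscle, proliferation, spongiotrophoblast and glycoprotein lists were lost, 4 without female control replicate 1 and 3 without female control replicate 4. Leaving out female benzene replicate 1 or 4 or female control replicate 1, 2 or 3 gave 15, 14, 15, 17 and 16 lists in all. Female benzene replicate 3 held 91.5 CPM of Myh11 and 35.1 of Actg2, the other benzene females 23.8 to 28.3 and 2.05 to 4.96.

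Lists tied to benzene metabolism and DNA damage were not called in females. The xenobiotic list had a median of -0.14 (camera adjusted p = 0.0762) and the p53 list -0.02 (adjusted p = 0.685). Cyp2e1, the main benzene-oxidizing enzyme, was looked at after the values had been seen. It averaged 12 ± 15.1 CPM with benzene and 45.1 ± 24.3 without (-1.91, SE 1.42) and followed the litter: over both sexes its mean was 69.3 and 28.2 CPM in the litters of control mothers 1 and 2, and 27.1 and 0.0585 in those of benzene mothers 1 and 2. Without the litter of benzene mother 1 the female comparison called 325 genes, 159 higher and 166 lower with benzene, and without the litter of benzene mother 2 it called 0. Each of these fits leaves 1 benzene mother, so the 325 belong to the litter of benzene mother 2 as much as to benzene.

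**Figure D2:**
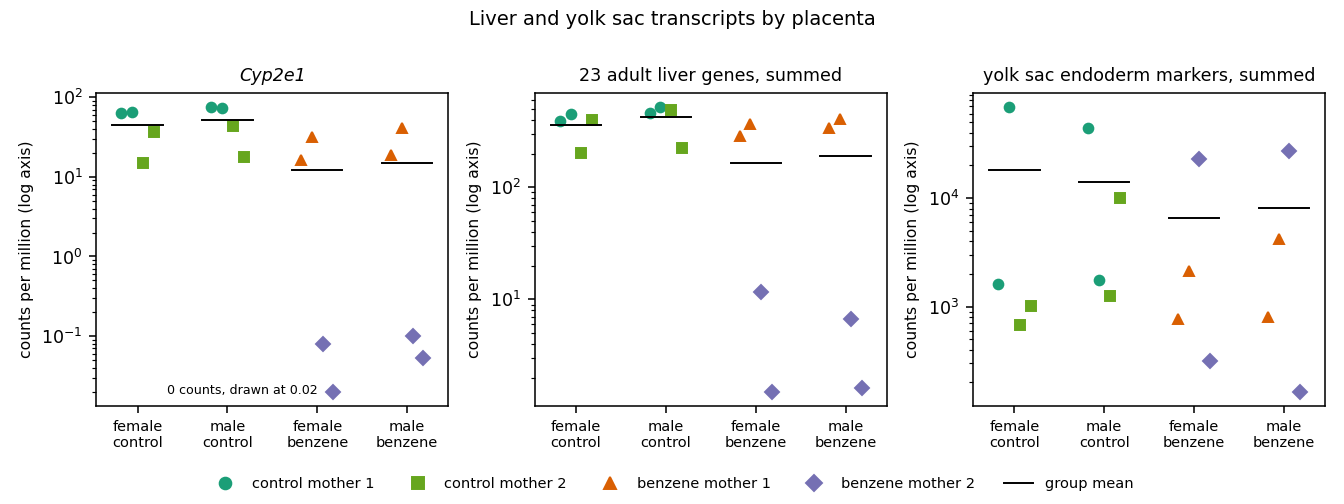
Cyp2e1, 23 adult liver genes summed and yolk sac endoderm markers summed per placenta in CPM on log axes, by sex and exposure, coloured by mother, with bars at group means. Liver genes are near absent in the 4 placentas of benzene mother 2, while yolk sac markers vary within each litter.

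What did benzene change in male placentas? By edgeR no gene and, with the correlation between genes estimated, no gene list passed adjustment in males (16 lists at the preset correlation, 0 with it estimated), so what follows are leanings. Male placentas leaned toward more transcripts of secretory protein handling and of the junctional zone, and fewer of vessel genes. Of 22 unfolded protein response genes 21 lay above control, 5 of them past the threshold when adjusted over the list alone and 0 over all genes (median 0.38, camera adjusted p = 5.43e-11, estimated-correlation p = 0.00659 before adjustment, not called after it). Trib3 averaged 19.5 ± 3.87 CPM with benzene and 13.8 ± 1.49 without (0.50, SE 0.14), with Atf4 at 0.33 and every benzene male above every control male for both. Control litters differed here. The summed list was at 10800 and 12600 CPM (on total counts) in the males of control mother 1 and 16100 and 16200 in those of control mother 2. It was at 15900 to 19300 with benzene, so the shift of the sum rests largely on control mother 1. Trib3 and Atf4, with every benzene male above the males of both control mothers, did not rest on control mother 1 alone. All 12 spongiotrophoblast genes lay above control (median 0.47, estimated-correlation p = 0.0375), with Tpbpa at 0.58, Tpbpb at 0.64 and Prl2a1 at 0.48. Their sum (on total counts, as for the next lists) was 23000 and 29800 CPM in the males of control mother 1. It was 32900 and 38500 in those of control mother 2, within the 30700 to 47500 seen with benzene. All 20 pregnancy-specific glycoprotein genes (median 0.42) and all 49 ribosomal protein genes (0.14) also lay above control. Giant cell genes had a median of 0.28 with Prl7a1 at 1.05 and Hand1 at 0.44. Summed glycoproteins were at 56900 and 70700 CPM in males of control mother 1, 77400 and 89600 for control mother 2 and 72200 to 111000 with benzene. Giant cell sums in that order were 23200 and 25400, 31100 and 33500, and 26500 to 32300. Ribosomal sums were 7490 in male benzene replicate 4, 8610 to 8760 in the other benzene males and 7650 to 8480 in control males. Oxidative phosphorylation (0.17), hypoxia (0.14) and NRF2 target lists (0.07, with Mt1 at 0.53 and Hmox1 at 0.43) also leaned upward. Macrophage genes were split, the median being -0.55 with Cd163 at -1.28 and Adgre1 at -0.58 but Cd68 at 0.40 and Csf1r at 0.45. Their summed CPM (on total counts) was 1670 to 1920 with benzene and 1460 to 1650 without. Csf1r made up most of that sum, at 1350 to 1540 CPM with benzene and 931 to 1240 without, so the sum mainly follows that gene. Endothelial (-0.31, with Emcn at -0.62 and Tek at -0.51), proliferation (-0.35, with Top2a at -1.12), interferon (-0.23), smooth muscle (-0.37), inflammatory (-0.18), imprinted (-0.11) and xenobiotic lists (-0.39, with Cyp2e1 at 0.101 and 0.053 CPM in the males of benzene mother 2, 18.9 and 41.5 in those of benzene mother 1 and 18 to 74.6 in control males, like the liver genes near absent from that litter) leaned downward, and the p53 list was not called (median -0.004, adjusted p = 0.558).

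Single genes fell short of the threshold. The nearest was Pik3r1, which encodes the regulatory subunit of PI3 kinase (chromosome 13, 101680563 to 101768217), at 75.5 ± 2.54 CPM with benzene and 100 ± 3.24 without (-0.41, SE 0.06, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0697), followed by the translation repressor Eif4ebp1 (0.42, SE 0.07) and Hmcn1 (-1.09, SE 0.20) at 2.57 ± 0.543 and 5.46 ± 0.728 CPM. edgeR's quasi-likelihood test called 0 genes, with 2475 at unadjusted p under 0.05, DESeq2 called 332 (182 higher and 150 lower), and 0 were called by voom with the mother as a random effect or by counts summed per mother. For the 16 lists the estimated-correlation p ran from 0.00659 to 0.305. Without the litter of benzene mother 1 the comparison called 157 genes, 58 higher and 99 lower, and without the litter of benzene mother 2 it called 0, each with 1 benzene mother left, so the 157 cannot be parted from the litter of benzene mother 2.

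Did benzene act differently in the 2 sexes? The interaction, the female minus the male effect of benzene, had 0 called genes by edgeR (1555 at unadjusted p under 0.05, smallest Benjamini-Hochberg adjusted p 0.362). The smallest p belonged to Hmcn1 (1.67, SE 0.27), followed among others by Pik3r1 (0.43), Prl2a1 (-0.90) and C5ar2 (-1.39), with Trib3 at -0.77. With the mother as a block 1 gene was called, Hmcn1, DESeq2 called 35 (13 positive and 22 negative), and voom with a random effect and mother sums called 0. Of the gene lists, 14 passed for the interaction at the preset correlation and 0 with the correlation estimated, so the list differences here are leanings. The trophoblast and unfolded protein response lists that leaned upward in males leaned less or downward in females, with interaction medians of -0.67 for spongiotrophoblast and -0.51 for the unfolded protein response, while smooth muscle (0.85) and proliferation genes (0.75), for which female benzene replicate 3 stood apart, and macrophage genes (0.58) went the other way. Across all 17392 genes the benzene effects in females and males were correlated with r = 0.302, and 56.6% of genes had the same sign. When each sex was given litters of different mothers, r lay between -0.305 and 0.0607 in the 4 arrangements of mothers, so the shared part was not seen across litters.

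**Figure D3:**
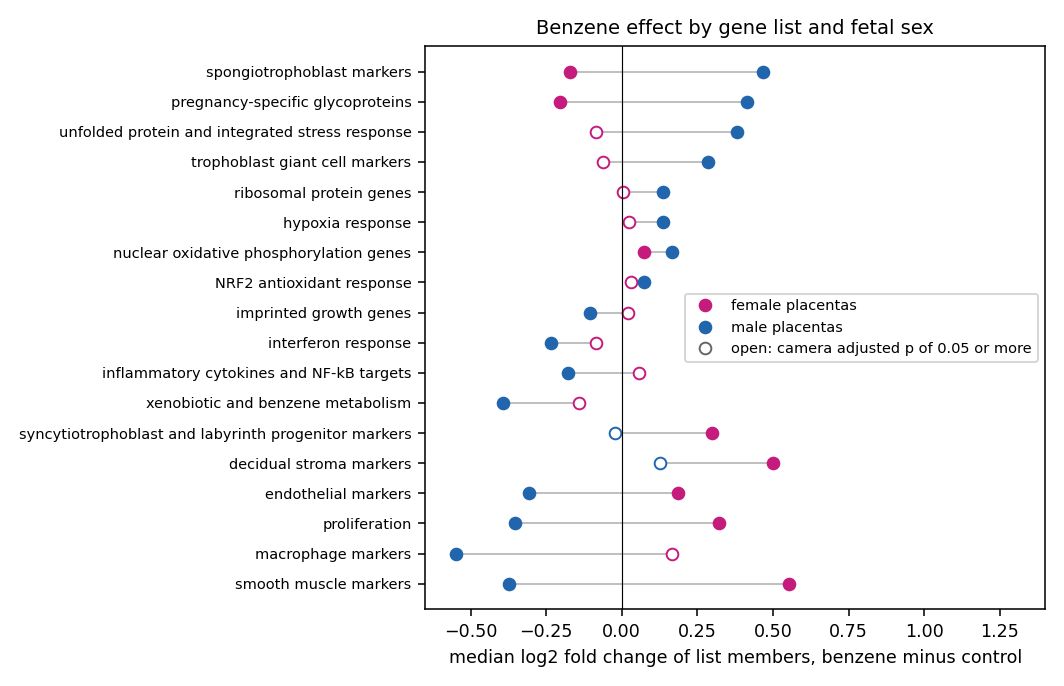
Median log2 fold change of benzene against control per gene list in female and male placentas. Filled points passed camera at its preset correlation and 0 passed with the correlation estimated. Unfolded protein response and trophoblast lists lie above 0 in males, and smooth muscle, endothelial and proliferation lists lie on opposite sides in the 2 sexes.

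What differed in the decidua? Benzene decidua held many more trophoblast transcripts than control decidua. Of 18 pregnancy-specific glycoproteins and related Ceacam genes 10 rose and 0 fell, 18 when adjusted over the list alone, among them Psg28 (4.15, SE 0.43, GRCm38 chromosome 7, 18422536 to 18432041) and Psg26 (4.55). Of 15 giant cell genes 2 rose, 11 when adjusted over the list alone: Prl3b1, placental lactogen II (4.49, SE 0.67, chromosome 13, 27241847 to 27249683), and the X-linked homeobox gene Rhox9 (1.93). Of 10 spongiotrophoblast genes 3 rose, 9 when adjusted over the list alone, with Prl8a8 at 4.09 and Prl8a9 at 3.39. Prl2b1 rose (4.74) as the 1 called gene of 12 in the glycogen cell list. Outside the lists the placental cathepsins Ctsr (4.92, SE 0.58, chromosome 13, 61159204 to 61164256) and Cts3 (4.04) and the matrix protein Fbln7 (4.17) rose, and the amino acid transporter Slc38a4 rose (2.66) as the 1 called gene of both the nutrient transporter and the imprinted list. Reads of the Psg, Ceacam, prolactin and cathepsin families can be shared between close copies, so which member rose is less certain than that the family did.

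The list medians were 3.59 for the glycoproteins, 2.59 for spongiotrophoblast and 2.5 for giant cells (camera adjusted p = 5.44e-93, 2.12e-34 and 5.58e-31), and -0.38 for 12 labyrinth genes (not called, adjusted p = 0.234). With the correlation estimated, p was 0.0288, 0.0337 and 0.0291, and 0 lists passed after adjustment. Uterine natural killer genes leaned upward (1.06, with Gzmd at 1.31 and Gzme at 1.26), as did glycogen cell (0.34), nutrient transporter (0.32), hypoxia (0.43), endothelial (0.62, with Pecam1 at 1.01) and decidual stroma genes (0.31). Yolk sac endoderm genes leaned downward (-2.92, with Fgb at -3.81 and Apoa4 at -3.38; 12 of 13 fell when adjusted over the list alone and 0 over all genes), and control replicate 1 carried much of this: the summed yolk sac CPM was 10900 and 2110 in controls and 1850 and 1870 with benzene, and Fgb 231 and 34.8 against 9.13 and 9.71. Lower medians were also seen for uterine epithelium (-0.76, with Krt19 and Cdh1 at -1.10), cholesterol synthesis (-0.38) and immediate early genes (-0.43). For the lists of this kind that lost their call, the estimated-correlation p was 0.0432 to 0.344. edgeR's quasi-likelihood test called 24 of 12478 genes, 24 higher and 0 lower (smallest Benjamini-Hochberg adjusted p 0.0224, 741 at unadjusted p under 0.05, DESeq2 57 with 50 higher and 7 lower). With 2 libraries per exposure the comparison is of 4 pieces of tissue: leaving out benzene replicate 1 or 2 gave 155 or 1970 calls and control replicate 1 or 2 29 or 62, and the calls of Rhox9 and Ceacam5 were each lost in at least 1 of these refits, in which 1 library stood against 2 and the spread came from the pair alone. The sample codes leave some doubt on the groups, since the code of control replicate 1 resembles those of the benzene libraries. Y-linked genes had 50 and 48 counts in the control libraries and 1 and 0 in the benzene libraries, so the level of male fetal transcripts differed along with exposure.

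**Figure D4:**
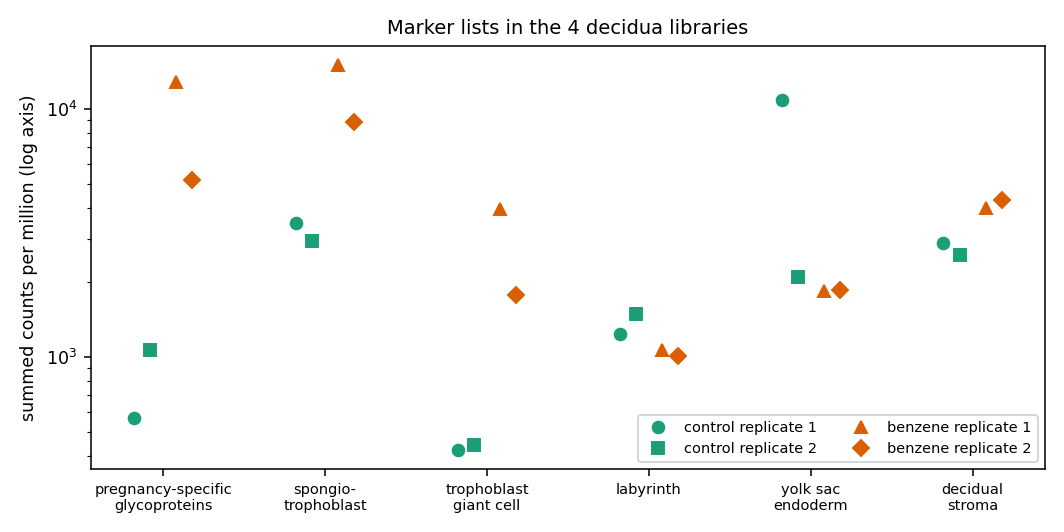
Summed CPM (on total counts) of 6 gene lists in the 4 decidua libraries, on a log axis, by exposure and replicate. Pregnancy-specific glycoproteins are at 12800 and 5150 with benzene and 568 and 1070 without, while labyrinth markers are at 1070 and 1010 with benzene and 1240 and 1490 without.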

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

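The tests of explanations and of other splits of the samples in this part were chosen after the results had been seen, while the interaction tests were planned. Group means were searched for libraries far from the other 3 of their group. Of 48 such tests 3 found one, where chance alone finds about 1 in 20: female benzene replicate 3 for total counts (24.3 M, the others 21.9 to 22.3) and for Il1b (0.678 CPM, the others 1.48 to 1.55), and male control replicate 1 for Trib3 (11.6 CPM, the others 14.4 to 14.7).

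By camera, 14 of 39 gene lists passed for the interaction at the preset correlation and 0 with the correlation estimated, so a difference between the sexes is not established. Medians of the interaction (female minus male effect) were negative for Psg genes (-0.629), spongiotrophoblast (-0.671), giant cells (-0.523), glycogen cells (-0.238), the unfolded protein response (-0.507), ribosomal proteins (-0.126) and oxidative phosphorylation (-0.075). They were positive for smooth muscle (0.852), proliferation (0.754), macrophages (0.579), endothelium (0.44), labyrinth (0.338), mesenchyme (0.309) and imprinted genes (0.149). Of the 14 medians none is thus more than a leaning. Among 100 groupings of the 16 placentas (the real one and 99 drawn at random) 35 gave at least as many lists (highest other 26). The random groupings mix sexes and litters and can carry their effects. They are thus a poor measure of chance for the interaction, and chance cannot be excluded.

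Other splits of the same libraries were fitted in the same way. For the control sex difference 1 of the 35 splits gave as many genes, the real one (35, highest other 4), the smallest share 35 splits can give. Only the real split parts the sexes, so the sex-linked genes among the 35 had to favour it. The splits were not rerun without X and Y genes, so they do not exclude chance for the other genes. Of the 23 genes without sex linkage higher in control males, 15 were called again in benzene placentas, which came from other mothers. The sum of the 23 was 99.7 CPM or more in every male and 51.4 or less in every female. These values argue against chance for that set. Of the 2 such genes higher in control females 0 were called again. As many lists were given by 28 of 35 splits (9, highest other 19). For the benzene sex difference 2 of 35 gave as many genes as the 29 called, and the other one, with 169 genes, was the split of the 2 litters from each other, which points to a litter structure in these samples. Among the 8 splits that part all 4 pairs of equal number, in which the others mix the sexes, the others gave 0 genes and 2 of the 8 gave as many as 16 lists (highest other 16). Of all 35, 8 gave as many lists (highest other 22). For benzene in females 32 of 35 gave at least 8 lists (highest other 20), and in males 3 of 35 gave at least 16 (highest other 19). Chance can therefore not be excluded for any list count in the placenta. The gene counts of benzene in females, in males and of the interaction were 0, and any split gives at least 0 (35 of 35, 35 of 35 and 100 of 100, highest others 7, 1 and 541), so splits test nothing there. In decidua, with 2 libraries against 2, the splits are too few for this.

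The first pattern weighed is that of 23 genes without sex linkage higher in control males, largely of activated myeloid cells, with a summed CPM of 158 to 196 in 6 males, 99.7 to 102 in the 2 males of benzene mother 2 and 30.8 to 51.4 in females. More macrophages in males is argued against: macrophage markers had a median of -0.12 (interval -0.22 to -0.01), the 23 genes -2.98. RNA or reads from one outside source of activated myeloid cells may have entered the male libraries: the 23 genes differed between the 2 low males and the other 6 by nearly one common factor (chi-square per degree of freedom 2.3), where 1000 random sets gave a median of 13 and a lowest value of 2.89. The 2 low males differed from each other in these genes by no more than counting noise (0.878, median of random sets 10.7, 0 of 1000 as low). The random sets were not chosen to vary together, and the 23 genes were called partly for a small spread within groups. Genes switched on together in resident cells could give one factor too, so neither value tells an outside source from resident cells. Sex of the fetus stays open, the lowest male to female ratio in a litter being 2.43, since every male library carries the signal and nothing in the design parts sex from the handling of male samples.

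The next pattern is that of adult liver genes in 3 of the 4 litters, which sets benzene mother 2's placentas apart. Their summed CPM was 196 to 492 in 12 placentas and 1.44 to 11.3 in the 4 of benzene mother 2. Yolk sac or fetal liver tissue is argued against, since the library of that litter with 17700 CPM of Afp held 7.29 CPM of the liver genes, and the library lowest in Afp (42.6 CPM) held 334. RNA or reads of liver shared by pairs of libraries is a candidate source. The 12 libraries fell into 6 female-male pairs that matched each other best. At most 0.001 of random gene sets did so, the smallest share 1000 sets can give, though random sets do not vary together as liver genes do. All 6 pairs were of littermates, so the pairing cannot tell a source shared by pairs from a state of the litter. A state of the mother or litter (mean 5.45 CPM in benzene mother 2's litter against 319 to 456 in the others) stays open, and benzene cannot be told apart from litter here, with 351 CPM in the litter of benzene mother 1. Handling of that 1 litter's samples cannot be told apart from a state of the litter either. The females of benzene mother 2 also held fewer Ddx3y counts (2 and 2, the other females 9 to 22). Their Kdm5d counts (1 and 0) also lay below those of the other females (4 to 6). Uty counts were 0 and 0 in them and 0 to 6 in the others. Their Eif2s3y counts (5 and 2) overlapped the others (3 to 12), and the cause was not tested.

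The last pattern is that of trophoblast genes in benzene decidua. More fetal tissue of every kind was weighed with the labyrinth markers. These had a median of -0.38 (interval -0.81 to 0.63), while spongiotrophoblast markers had 2.59 (0.96 to 3.39). The labyrinth list cannot decide this, since its member Epcam is also in the uterine epithelium list, which leaned downward. Epcam, Itga6 and Itgb4 lay lower with benzene and Tfap2c higher. Yolk sac endoderm markers, also of fetal tissue, had a median of -2.92 (-3.63 to -2.4). Their sum on total counts was 1850 and 1870 CPM with benzene and 10900 and 2110 without, so they rose above neither control. This argues against more fetal tissue of every kind, while more fetal tissue of some kinds stays open. A larger share of junctional zone stays open: giant cell markers moved with spongiotrophoblast (1.13 to 3.82). Glycogen cell markers, also of that zone, rose less, with a median of 0.34 (0.02 to 0.76). These lists did not rise alike, which does not show whether the zone rose as a whole. Benzene itself stays open: the Psg sum differed 2.18-fold between the 2 benzene libraries (11900 and 5470 CPM on TMM-scaled sizes, controls 608 and 1050), and the control libraries held 50 and 48 counts of Y-linked genes and the benzene libraries 1 and 0, so the level of male fetal transcripts differs along with exposure.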

How the results depend on the processing

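Settings chosen after results had been seen were the removal of libraries high in Afp, tissue covariates, removal of GC and length trends, leaving out a litter in the sex comparisons and taking both benzene effects from the same mothers; the others were planned. The cause of a moved count was not tested.

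For the control sex difference (35 genes) DESeq2 called 56 (13 higher in females, 43 in males), a block on replicate number 21 (2 and 19), leaving out control mother 1's litter 12 (1 and 11) or control mother 2's 13 (1 and 12), leaving out libraries with over 5000 CPM of Afp 23 (4 and 19), and leaving out X and Y genes 23 (1 and 22). Replicate numbers did not pair control placentas (r -0.49 to 0.365, 1 of 8 best matched), nor placentas across exposure (females -0.266 to 0.336, males -0.451 to 0.047). Leaving out 1 library gave 26 to 29. The block ended the calls of Rps4x, S100a6, Slc15a3, Slc7a11, Taf1 and Tlr2, and without the Afp-high libraries Tnf was not called in either sex comparison.

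For the benzene sex difference (29) DESeq2 called 289 (119 and 170), the 8 benzene libraries fitted alone 13 (1 and 12), the block on replicate number 18 (3 and 15), leaving out benzene mother 2's litter 18 (2 and 16), tissue covariates 19 (2 and 17) and no X and Y genes 19 (2 and 17). Leaving out 1 library gave 20 to 41. Hmcn1 and Trib3 were not called after removal of GC and length trends, nor Airn, Ogt, Taf1 and Trib3 with upper-quartile scaling.

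For benzene in females (0) DESeq2 called 46 (23 and 23) and the fit without benzene mother 1's litter 325 (159 and 166), without benzene mother 2's 0. In males (0) DESeq2 called 332 (182 and 150), the 8 male libraries alone 10 (1 and 9), the fit without benzene mother 1's litter 157 (58 and 99), without benzene mother 2's 0, and an adjusted p under 0.1 gave 38 (21 and 17). For the interaction (0) DESeq2 called 35 (13 and 22), the mother as a block 1 and the fit without benzene mother 1's litter 2, without benzene mother 2's 0. DESeq2 also called 21 to 28 unchanged genes on simulated placenta data. Leaving out 1 library gave 0 to 0 calls in these 3 comparisons.

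In decidua (24) upper-quartile scaling gave 15, no filter 170 (94 and 76), DESeq2 57 (50 and 7), a block on replicate number 62 (51 and 11), and an adjusted p under 0.1 37. Leaving out 1 library gave 29 to 1970: 155 without benzene replicate 1, 1970 (959 and 1011) without benzene replicate 2, 29 without control replicate 1 and 62 without control replicate 2, each with 1 library against 2 and the spread taken from the pair alone. Replicate numbers did not pair decidua libraries (r -0.0798).

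With the correlation estimated, called lists went from 9 to 2 and from 16 to 2 in the control and benzene sex differences, from 8 and 16 to 0 for benzene in females and males, from 14 to 0 for the interaction and from 13 to 0 in decidua. Leaving out 1 library gave 7 to 11, 14 to 19, 8 to 17, 12 to 18, 11 to 21 and 9 to 15 lists in that order. In females it was 15 without female benzene replicate 1, 14 without female benzene replicate 4, and 15, 17 and 16 without female control replicates 1, 2 and 3. The correlation of benzene effects between the sexes (0.302) was 0.592, 0.585, 0.636 and 0.139 with both effects from the same mothers and -0.147, 0.0607, 0.0293 and -0.305 with different mothers per sex. For the genes chosen for the text alone, over all alternatives, 3601 values had the same call as before, 183 lost a call, 192 gained one and 0 reversed. For the called lists 765 were the same and 195 lost.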

Other observations

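Beyond the sex difference, the male libraries of both exposures carried a set of innate immune transcripts. Besides the genes named above, the interleukin-1 antagonist Il1rn (-2.27 in controls), the receptor Tlr2 (-1.47) and the chemokines Ccl7 and Ccl9 were higher in control males, while Cd14 (-0.86, adjusted p 0.238) was not called; Il1rn and Tlr2 were looked at after the values had been seen. Within benzene males the litters differed, with Il1b at a mean of 11.7 CPM in the litter of benzene mother 1 and 6.57 in that of benzene mother 2.

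In decidua, the glucose transporter Slc2a1 (0.89) and the immediate early gene Fos (-1.23) were among the smallest p of their lists without being called.

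The test in this paragraph was chosen after the values were seen. Xist in male placentas varied from 47.7 to 119 CPM and may come from maternal decidual RNA. Over 8 male placentas it followed the mean of 15 decidual stroma markers with r = 0.868 (exact permutation p = 0.00623) and rho = 0.905 (exact permutation p = 0.00456). Without the 2 farthest placentas r was 0.698, and the order was the same in 4 of 4 litters. The permutations treated all 8 males as independent although they include littermates, so these p can be too small.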
